A study of Homo sapiens with 8 samples.

How the data were processed

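Gene expression was measured by RNA sequencing in 8 libraries of human airway basal stem cells, the progenitor cells of the airway lining. The cells were grown from tracheal aspirates as 2 lines, BSC11 and BSC13, in a growth medium for small airway epithelium. Per the labels' protocols, the medium held A-83-01, an inhibitor of the TGF-beta receptor kinase, and Y-27632, an inhibitor of the kinase ROCK. Each line was cultured without rapamycin or with 5 nM rapamycin, an inhibitor of the kinase mTOR. The length of treatment and the passage number are not given in the sources used here.

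The authors deposited 1 table of read counts per gene symbol, with a column for each of the 8 libraries. Libraries were prepared with a TruSeq v2 kit, per the labels' protocols. STAR 2.6.0a, HTSeq 0.5.3p9 and the genome build GRCh38 are named in the submitters' processing notes. The annotation, the strand setting and any filter are not given in the sources used here. The counts are whole numbers, the column totals differ, and no row holds unassigned reads. Of the 20310 genes in the table, 19764 (97.3%) are coding genes in GENCODE 29 and 3887 had 0 counts in all 8 libraries, so non-coding RNA was barely measured. Counts are of reads without molecular identifiers, so depth and counting intervals cover counting error only. Where the strand was not used in counting, reads of genes that overlap on opposite strands cannot be told apart, and reads shared by near-identical genes may have been split or dropped.

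Libraries were grouped by line and agent as the labels give them, which made 4 groups of 2 libraries. The labels do not say whether the replicates were separate cultures. Library totals were 12800928 to 17646289 counts. The 45 genes of the Y chromosome were left out of every test and table. The 12622 genes that passed edgeR's filterByExpr (minimum count 10) were tested.

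The main test was edgeR 4.0.16 (R 4.3.3): TMM scaling, a model with a mean for each of the 4 groups, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment with a threshold of 0.05. All 8 libraries shared one estimate of the spread, with 4 residual degrees of freedom. The contrasts were the rapamycin response averaged over both lines, the response of each line, the difference between these responses, and the difference between the untreated lines. Levels are CPM, counts scaled to a common library total with the TMM factors, as mean ± SD of 2 libraries, and log2 fold changes carry the standard error of the model. Changes are relative to the other genes of a library.

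Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 39 of 42 lists that had at least 5 tested members. Camera asks whether the genes of a list rank apart from all other genes. The test was repeated with the correlation estimated per list, and with fry, which asks whether the genes of a list move, on balance, one way. Counts of members that rose or fell use the adjustment over all 12622 genes, and counts adjusted over the list alone stand beside them. The lists were written from general knowledge, not from these samples.

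Genes were named by a rule. For the averaged response these were the 10 largest rises and the 10 largest falls among called genes with a mean of at least 8 CPM whose rapamycin libraries lay on the same side of the untreated libraries in both lines. In each list, up to 2 rising and 2 falling called members with the smallest p could be named. A fixed set of 17 genes was reported in any case. For the difference between lines, the 5 genes with the smallest p in each direction were named. No gene was named for the difference between the untreated lines. Of the genes the rule allows per list, only some appear in the text. The groups, contrasts, lists, naming rule and most alternatives were fixed before the data were examined.

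Where a group held 3 counts or fewer of a named gene over its 2 libraries, fitted fold changes were not used to give its size. With 0 counts, the fold was computed against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with its exact 95% counting interval. Differences between lines in such genes were computed from the same counts. The same was done where leaving out a library left 3 counts or fewer in a group. Gene positions are those of GENCODE 29 on GRCh38.

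The alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, library totals alone, no low-count filter, a filter of 1 CPM in all libraries, the replicate number as a block, a test against a 1.5-fold change, an additive model, a model without the line, separate fits per line, and leaving out each library in turn. For gene lists, fry and a prior count of 0.5 were also run. Leaving out a library leaves its group with 1 library and no spread of its own. P-values and counts of called genes from such fits then rest on the spread of the other groups. Without an untreated BSC11 library the most spread pair is gone and more genes pass. Such counts change with the shared spread as well as with the levels in the library left out. By themselves they do not show that a result depends on 1 library, and they are not stronger evidence. The BSC13 response does not use the untreated BSC11 libraries, so its counts without 1 of them change mainly through the spread. Added after seeing the data were a voom fit with one weight per group, a fit with a trend on transcript length and GC content removed from each library (values for 99.7% of tested genes), list counts without 1 of the untreated BSC11 libraries and in BSC13 alone, and the contrast of the lines under rapamycin.

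The test was checked on simulated counts for 12622 genes with 200 of them changed, 3 simulations per setting. With one dispersion for all groups, the averaged response recovered 52.7% of the 2-fold and 91.4% of the 4-fold changes, and 7% of its calls were false. With each group's own dispersion, as estimated from its pair of libraries, it recovered 32.3% and 92.4%, with 3.3% false. In that second setting 45.6% of the calls for BSC11 were false, while BSC13 had 0% false calls and recovered 1.5% of 2-fold changes. The difference between lines recovered 30.3% of 4-fold changes with one dispersion and 3.5% with each group's own. Far more genes were called in the data (4753 for the average) than were changed in the simulations. The second setting also gave all genes of a group the same dispersion. These shares therefore do not carry over to the data as rates.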

Results

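RNA was sequenced from airway basal stem cells, the progenitors that renew the lining of the airway, grown in culture from human tracheal aspirates. The design asked how these cells differ when mTOR, a kinase that couples nutrient supply to growth, is inhibited. The lines BSC11 and BSC13 were each cultured without rapamycin or with 5 nM rapamycin, and each of the 4 groups had 2 libraries. The untreated BSC11 libraries held 17646289 and 12800928 counts, and the BSC11 rapamycin libraries 14136650 and 15429304. The untreated BSC13 libraries held 17006479 and 14972861 counts, and the BSC13 rapamycin libraries 17209204 and 15438507. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

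The untreated BSC11 libraries stood apart from the other 6 and from each other. On the first principal component, which held 50.2% of the variance, they lay at -86.8 and -115.3, and the other libraries at 24.4 to 51.9. Between the untreated BSC11 replicates the SD of log2 differences over genes was 0.93, against 0.3, 0.3 and 0.39 in the other pairs, and 2486 genes differed more than 2-fold, against 176 to 402. No pair agreed within sampling noise (chi-square per degree of freedom 4.33 to 202). All 29 tested genes of the mitosis list were higher in untreated BSC11 replicate 1 than in replicate 2, by a median of 3.26 on the log2 scale. DNA replication genes were higher there too, by a median of 1.11, and genes of squamous differentiation were lower, by a median of -1. Mitochondrially encoded genes took 12.7% of the counts of replicate 2 and 4.3% of those of replicate 1, against 2% to 3.75% in the other libraries. Across genes, which are not independent replicates, the deviation of a gene from its mean correlated with transcript length in the untreated BSC11 libraries (Spearman's rho 0.36 and 0.28), against -0.29 to -0.03 elsewhere. With GC content, rho was -0.03 and 0.08 in these libraries. It was 0.31 in BSC11 rapamycin replicate 2, and -0.48 in BSC13 rapamycin replicate 2 against -0.08 in replicate 1. Trends with transcript composition were therefore not confined to the untreated BSC11 libraries.

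Averaged over both lines, cells grown with rapamycin had far lower levels of squamous differentiation genes, which mark the step from basal cell to stratified, cornifying epithelium, and of interferon-stimulated genes. Genes of ribosome biogenesis, of the actin cytoskeleton and YAP target genes, and chaperones were higher. Camera called these 5 lists, but with an estimated correlation none passed (adjusted p = 0.42, 0.57, 0.097, 0.55 and 0.42, in the order named). Of 12622 genes tested, 2164 rose and 2589 fell. Large changes were mostly falls: 466 genes rose and 1392 fell by more than 2-fold. In 3188 of the 4753 called genes (67.1%) both rapamycin libraries lay on the same side of both untreated libraries in both lines. Among all tested genes this held for 31.2%. Chance gives 5.6% only if the libraries of a line are exchangeable. If replicates share a culture it gives more, so the share does not measure an effect of rapamycin.

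Among genes with a mean of at least 8 CPM and separate libraries in both lines, the 10 largest falls included several genes of the differentiating epithelium. KRT4, a keratin of suprabasal cells in moist stratified epithelium (chromosome 12, 52806549 to 52814551), dropped from 1160 ± 226 to 34.8 ± 0.0321 CPM in BSC11 and from 1110 ± 27.4 to 19.2 ± 1.26 CPM in BSC13 (SD, n = 2). Its log2 fold change was -5.45 ± 0.15 (SE), with an adjusted p of 2.16e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. KRT6C (-6.02 ± 0.24), a keratin with near-identical paralogs whose reads it may share, and the desmosomal cadherin DSG1 (-5.57 ± 0.42) fell too. So did the chemokine CXCL14 (-6.71 ± 0.88), C10orf99 (-6.52 ± 0.78), which encodes an epithelial antimicrobial peptide, the growth factor BMP7 (-5.92 ± 0.61) and the interferon-induced IFI27 (-5.45 ± 1.02). TGM3, a transglutaminase that crosslinks the cornified envelope, dropped from 139 ± 122 to 0.17 ± 0.0568 CPM in BSC11. In BSC13 it dropped from 2505 counts to 1 count, a ratio of 2680 (95% counting interval 480 to 106000), and without BSC13 rapamycin replicate 2, which held that count, it was at least 468-fold lower. ENDOU, an endoribonuclease, had 719 counts in untreated BSC11 and 0 with rapamycin, which makes it at least 222-fold lower, and it dropped from 41.8 ± 7.89 to 0.279 ± 0.0623 CPM in BSC13. ALDH1A1, which makes retinoic acid, dropped from 53.4 ± 59.3 to 0.17 ± 0.0568 CPM in BSC11 and from 13 counts to 2 in BSC13, a ratio of 6.95 (1.57 to 63.4). Without untreated BSC11 replicate 1 the falls stayed called but were smaller: -5.27 for CXCL14, -5.35 for C10orf99, -5.27 for BMP7, -4.85 for DSG1 and -4.18 for IFI27. Leaving out BSC11 rapamycin replicate 2 left BMP7 with 0 counts in that group, at least 261-fold lower than untreated BSC11. Leaving out untreated BSC13 replicate 2 took IFI27 to -4.72, and without untreated BSC13 replicate 1 ALDH1A1 was no longer called (edgeR adjusted p = 0.0715). In BSC13 alone IFI27 was not called (-3.16 ± 1.48, edgeR adjusted p = 0.193), nor was ALDH1A1 (adjusted p = 0.433). In limma-voom neither IFI27 (adjusted p = 0.0942) nor ALDH1A1 (adjusted p = 0.121) was called.

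Among genes with a mean of at least 8 CPM and separate libraries in both lines, the largest rise was in KRT23, a keratin inducible in simple and stressed epithelium (chromosome 17, 40922696 to 40937634), with a log2 fold change of 5.29 ± 0.28 (edgeR adjusted p = 9.05e-05). Most of it came from BSC11, where KRT23 rose from 0.848 ± 0.775 to 349 ± 3.46 CPM, against 148 ± 0.754 to 596 ± 14.1 CPM in BSC13. VIM, the intermediate filament protein vimentin, rose by 4.35 ± 0.42, from 0.605 ± 0.628 to 3.1 ± 0.315 CPM in BSC11 and from 0.493 ± 0.00226 to 37.9 ± 7.86 CPM in BSC13. THBS1, the matrix protein thrombospondin 1 and a YAP target (chromosome 15, 39581079 to 39599466), rose from 46.6 ± 24.8 to 1160 ± 38.6 CPM in BSC11 and from 73.7 ± 8.51 to 1020 ± 49 CPM in BSC13. FSIP1 (3.64 ± 0.18) overlaps THBS1 on the opposite strand (39588357 to 39782830), so its rise may hold THBS1 reads and is uncertain. The other rises were in FST (4.02 ± 0.5), which encodes follistatin, a secreted antagonist of activins, the palmitoyltransferase ZDHHC2 (3.62 ± 0.15), and the acute-phase gene SAA1 (3.56 ± 0.14), whose reads may be shared with a near-identical neighbour. TGFB2 (3.2 ± 0.29), which encodes a TGF-beta ligand, RTL6 (3.01 ± 0.26), and the secreted Wnt antagonist DKK1 (3 ± 0.39) completed the 10. The average of RTL6 came from BSC11 (0.621 ± 0.499 to 28.3 ± 1.2 CPM), and in BSC13 it was not called (16 ± 0.329 to 21.5 ± 2.62 CPM, edgeR adjusted p = 0.395). Without untreated BSC11 replicate 2 the rise was 4.93 for FST and 3.7 for DKK1, and without replicate 1 it was 6.07 for KRT23. Without replicate 2, VIM went from 3 counts to 92 in BSC11, a ratio of 19.3 (95% counting interval 6.4 to 95.3).

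**Figure D1:**
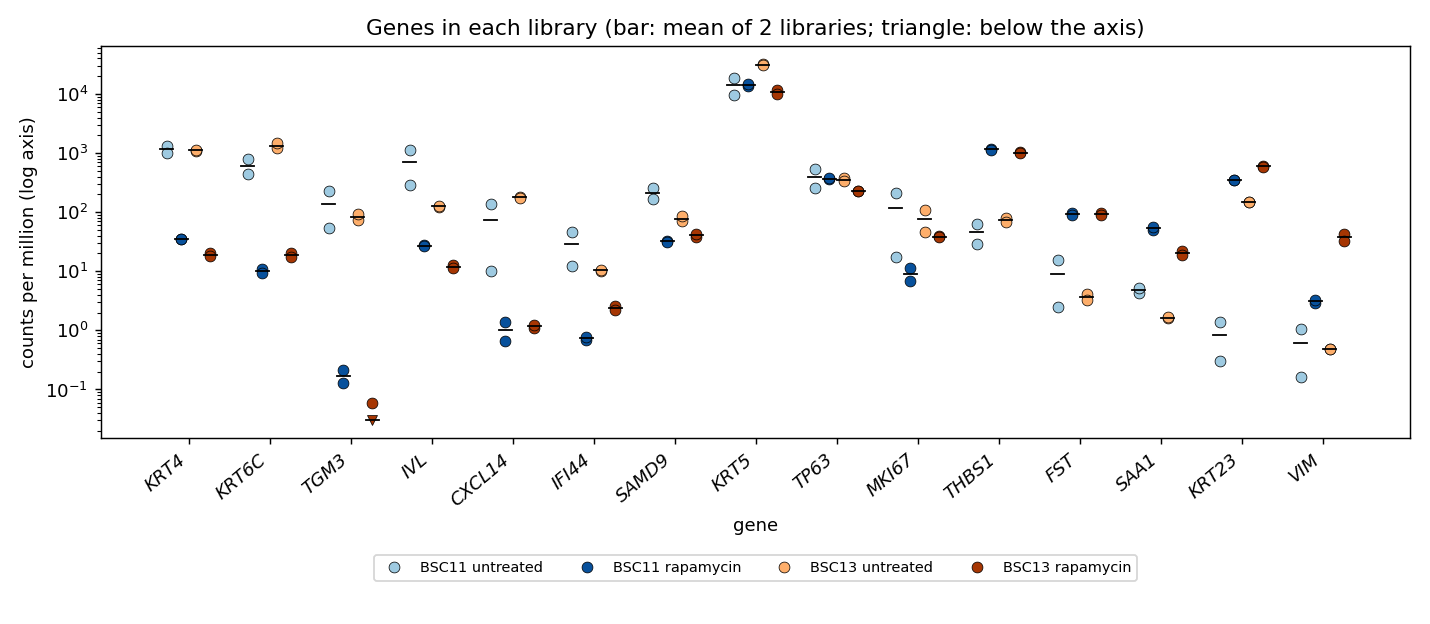
CPM (log axis) of 15 genes in each of the 8 libraries; points are libraries, coloured by line and agent, bars are the mean of 2 libraries, and a triangle marks a value below the axis. KRT4 lies at 995.62 to 1315.13 CPM in the 4 untreated libraries and at 18.33 to 34.79 CPM in the 4 rapamycin libraries, and the untreated BSC11 libraries are the most spread for MKI67 and CXCL14.

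Of the 51 genes of the squamous differentiation list, 43 fell and 8 were not called (46 fell adjusted over the list alone), with a median log2 fold change of -2.74, or -2.64 with the 6 genes near 0 counts at their bound. IVL, the cornified envelope protein involucrin, fell by 4.05 ± 0.41 (SE) on the log2 scale, and by 3.4 without untreated BSC11 replicate 2. Camera ranked the list far below other genes (adjusted p = 2.2e-17, and adjusted p = 0.42 with an estimated correlation). The fall was also seen without untreated BSC11 replicate 1 (49 of 51) or replicate 2 (44 of 51, with 2 rising), and in BSC13 alone (49 of 51). Of 31 interferon-stimulated genes, 25 fell (27 adjusted over the list alone), with a median of -2.15, or -2.08 with the 4 genes near 0 counts at their bound (camera adjusted p = 3.1e-08, and adjusted p = 0.57 with an estimated correlation). SAMD9, an antiviral factor, fell by 1.83 ± 0.15 and IFI44 by 3.71 ± 0.45, or by 3.07 without untreated BSC11 replicate 1.

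Lists of cell contact and cell fate also shifted down. So did the replication-dependent histone and mitochondrially encoded lists, which were classed as measures of RNA quality and not as pathways. In the epithelial junction list 15 of 27 genes fell and 2 rose (16 and 3 adjusted over the list alone), led by the desmosomal cadherin DSG3 at -1.73 ± 0.11 (camera adjusted p = 0.0042, and adjusted p = 0.42 with an estimated correlation). In the Notch pathway 8 of 17 fell (9 adjusted over the list alone), among them the receptor NOTCH3 at -3.21 ± 0.3 (camera adjusted p = 0.0042, and adjusted p = 0.42 with an estimated correlation). In the matrix and adhesion list 14 of 28 fell and 4 rose (18 and 4 adjusted over the list alone), TGFBI falling by 2.86 ± 0.13 while THBS1 rose (camera adjusted p = 0.015, and adjusted p = 0.42 with an estimated correlation). This fall came mainly from BSC11, where 18 fell and 3 rose (median -1.08, camera adjusted p = 0.0039). In BSC13 5 fell and 4 rose (median -0.33), and camera did not call the list (adjusted p = 0.6). Secretory cell markers fell in 10 of 17 tested genes and rose in 3, the same counts as adjusted over the list alone (camera adjusted p = 0.036, and adjusted p = 0.75 with an estimated correlation). Camera called them in BSC13, where 8 fell and 0 rose (median -1.64, adjusted p = 0.0029). It did not in BSC11, where 5 fell and 3 rose (median -0.78, adjusted p = 0.59). FOXO targets fell in 12 of 23 and rose in 3 (13 and 3 adjusted over the list alone, camera adjusted p = 0.03, and adjusted p = 0.42 with an estimated correlation). Of 10 replication-dependent histone genes 5 fell (6 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.036, and adjusted p = 0.63 with an estimated correlation). This fall came from BSC13 (median -1.64), while in BSC11 4 rose and 2 fell (median 0.07). Of 13 mitochondrially encoded genes, whose share was highest in untreated BSC11 replicate 2, 5 fell (5 adjusted over the list alone, camera adjusted p = 0.03, and adjusted p = 0.88 with an estimated correlation). Without replicate 1 of that group all 13 of the last list fell. Without replicate 2 camera no longer called the junction, matrix, secretory, histone and mitochondrially encoded lists (adjusted p = 0.06, 0.06, 0.085, 0.2 and 0.1).

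Among the lists that shifted up, ribosome biogenesis had the largest share of rising genes. In it 26 of 31 rose and 1 fell, the same counts as adjusted over the list alone, with a median of 0.72 (camera adjusted p = 3.7e-08, and adjusted p = 0.097 with an estimated correlation). Its small-subunit factors PNO1 and UTP4 rose by 0.91 ± 0.1 and 0.85 ± 0.08. YAP targets and actin cytoskeleton genes rose in 16 of 28 and fell in 1 (17 and 2 adjusted over the list alone), the receptor kinase AXL by 1.91 ± 0.14 (camera adjusted p = 8.1e-05, and adjusted p = 0.55 with an estimated correlation). Chaperones rose in 13 of 19 and fell in 1 (14 and 2 adjusted over the list alone), DNAJA1 by 1.05 ± 0.1 (camera adjusted p = 2e-04, and adjusted p = 0.42 with an estimated correlation). Immediate early genes rose in 10 of 23 and fell in 2 (15 and 2 adjusted over the list alone, camera adjusted p = 0.0049, and adjusted p = 0.69 with an estimated correlation). Their median level was -0.8 and 0.51 in untreated BSC11 replicates 1 and 2, against 0.7 and 0.83 in the BSC11 rapamycin libraries. The size of the rise in BSC11 therefore depends on the untreated library. In BSC11 alone camera did not call these genes (adjusted p = 0.069). Among them MYC rose by 0.76 ± 0.09 in the average, which came from BSC13 (49.4 ± 3.12 to 170 ± 7.58 CPM). In BSC11 it went from 188 ± 12.8 to 157 ± 2.95 CPM and was not called (edgeR adjusted p = 0.13). Cholesterol synthesis genes rose in 9 of 23 (10 adjusted over the list alone), INSIG1 by 1.48 ± 0.15 and FDFT1 by 1.22 ± 0.12 (camera adjusted p = 0.0016, and adjusted p = 0.57 with an estimated correlation). Nucleotide synthesis genes rose in 8 of 20 (8 adjusted over the list alone, camera adjusted p = 0.0021, and adjusted p = 0.64 with an estimated correlation). Translation factors rose in 7 of 22 and fell in 2 (10 and 2 adjusted over the list alone, camera adjusted p = 0.0024, and adjusted p = 0.55 with an estimated correlation). Proteasome genes rose in 9 of 27 (9 adjusted over the list alone, camera adjusted p = 0.0046, and adjusted p = 0.64 with an estimated correlation). That rise came from BSC11, since in BSC13 none of the 27 was called (median -0.12).

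In several of these lists the count of members that rose changed when an untreated BSC11 library was left out. Part of such a change can come from the shared spread, which then narrows. For DNA replication, cytosolic ribosomal proteins and the nuclear respiratory chain the medians in BSC13 were 0.02, 0.01 and -0.14, so the averaged rises came from BSC11. Fry did not call any of them for the average (adjusted p = 0.15, 0.19 and 0.19). DNA replication genes rose in 12 of 30 and fell in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 0.00049, and adjusted p = 0.87 with an estimated correlation). In it 26 rose without untreated BSC11 replicate 1 and 20 without replicate 2. Genes of cytosolic ribosomal proteins had a median of 0.54, and 3 of 36 were called higher (camera adjusted p = 8.6e-05, and adjusted p = 0.87 with an estimated correlation). Adjusted over the list alone none was called, while 36 rose without replicate 1 (median 0.91) and 28 without replicate 2 (median 0.32). Nuclear genes of the respiratory chain rose in 6 of 33 and none was called adjusted over the list alone (camera adjusted p = 0.0073, and adjusted p = 0.87 with an estimated correlation). In it 24 rose without replicate 1, and without replicate 2, 12 rose and camera no longer called the list (adjusted p = 0.06). Without replicate 1, 16 of 20 nucleotide synthesis genes, 18 of 22 translation factors, 18 of 27 proteasome genes and 15 of 24 cholesterol synthesis genes rose. Without replicate 2 the counts were 12, 15, 15 and 16.

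Markers of basal cell identity did not pass camera as a list, while fry called the list lower (adjusted p = 0.012). Of 30 basal cell markers, 3 rose and 8 fell (2 and 8 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 0.088, and adjusted p = 0.64 with an estimated correlation). With untreated BSC11 replicate 1 left out 5 rose and 13 fell, with a median of -0.25, and with replicate 2 left out 8 rose and 18 fell. With the trend on transcript length and GC content removed the median was -0.23. TP63, the transcription factor of basal cells, had a log2 fold change of -0.37 ± 0.22, KRT5 of -0.77 ± 0.28, KRT14 of -0.57 ± 0.38 and NGFR of -0.47 ± 0.64, none called in edgeR (adjusted p = 0.224, 0.067, 0.275 and 0.588). KRT14 stood at 0.86 ± 0.55 in BSC11 and at -2 ± 0.56 in BSC13 (edgeR adjusted p = 0.236 and 0.054). SOX2, a transcription factor of the airway lineage, fell, with a log2 fold change of -4.65 ± 0.36 (edgeR adjusted p = 0.000275), and CAV1, which encodes caveolin 1, rose by 1.12 ± 0.17. Without BSC11 rapamycin replicate 2, SOX2 went from 254 counts to 1 in BSC11, a ratio of 113 (95% counting interval 20.1 to 4490). Several of these values hung on 1 untreated BSC11 library. A fit without it leaves that group no spread of its own, so only sizes are given. Without replicate 2 the log2 fold change was -0.59 for TP63, -0.87 for KRT14 and -0.91 for NGFR. Without replicate 1 NGFR stood at 1.06, with the opposite sign. KRT5 stood at -0.48 without replicate 1 and at -0.96 without replicate 2. DESeq2 with all libraries called KRT5 lower (-0.76, adjusted p = 0.00264).

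Proliferation and senescence genes gave no common direction. The mitosis list had a median of 0.35 with 1 of 29 genes called, MKI67, and none adjusted over the list alone (camera adjusted p = 0.088, and adjusted p = 0.93 with an estimated correlation). With untreated BSC11 replicate 1 left out the median was 1.49, and without replicate 2 it was -0.06. MKI67, the antigen Ki-67 of cycling cells, had a log2 fold change of -2.34 ± 0.71 (edgeR adjusted p = 0.037), with -3.67 ± 1.06 in BSC11 and -1.01 ± 0.95 in BSC13, where it was not called (adjusted p = 0.516). The average was -0.97 without untreated BSC11 replicate 1, and was not called without any 1 of the BSC11 rapamycin libraries or the 4 BSC13 libraries (edgeR adjusted p = 0.061 to 0.124), nor in limma-voom (adjusted p = 0.128). Senescence regulators rose in 3 and fell in 4 of 18 (3 and 4 adjusted over the list alone, camera adjusted p = 0.83, and adjusted p = 0.93 with an estimated correlation). In that list 10 rose and 4 fell without untreated BSC11 replicate 1, and 5 rose and 8 fell without replicate 2. The cell cycle inhibitor CDKN2B fell by 1.15 ± 0.11 and BMI1, a repressor of the CDKN2A locus, rose by 1.01 ± 0.19. CDKN1A, which encodes p21, had a log2 fold change of -0.36 ± 0.18 and CDKN2A, which encodes p16, of 0.51 ± 0.2 (edgeR adjusted p = 0.158 and 0.0789). CDKN1A stood at 0.41 ± 0.26 in BSC11 (edgeR adjusted p = 0.236) and fell by 1.14 ± 0.26 in BSC13 (adjusted p = 0.0301). Without untreated BSC11 replicate 2 CDKN1A stood at -0.52 and CDKN2A at 0.74, and without replicate 1 CDKN2A stood at 0.33.

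Factors that senescent cells secrete rose in 5 and fell in 8 of 35 (6 and 9 adjusted over the list alone, camera adjusted p = 0.82, and adjusted p = 0.93 with an estimated correlation). Leaving out untreated BSC11 replicate 1, 10 rose and 16 fell (camera adjusted p = 0.13), and without replicate 2, 19 rose and 10 fell (adjusted p = 0.014). IL1B, an inflammatory cytokine, rose by 0.79 ± 0.09 in edgeR, from 224 ± 3.53 to 348 ± 6.05 CPM in BSC11 and from 184 ± 5.85 to 355 ± 14.1 CPM in BSC13. IGFBP3 fell by 2.15 ± 0.28 in the average, which came from BSC13 (-3.98 ± 0.43), while in BSC11 it was not called (-0.32 ± 0.36, edgeR adjusted p = 0.509). CXCL8 stood at -0.22 ± 0.37 (edgeR adjusted p = 0.668), or at -0.54 without untreated BSC11 replicate 1. IL6 had 9 counts in all 8 libraries, and SCGB1A1 and FOXJ1, markers of club and ciliated cells, had 5 and 0, so changes in these were not detectable at this depth. In the fixed set of genes, RNA of the target kinase and of the partners named there showed no called change. MTOR stood at 0 ± 0.09, RPTOR at -0.05 ± 0.21 and DEPTOR at -0.41 ± 0.41 (edgeR adjusted p = 1, 0.865 and 0.46). Other members of the mTOR and PI3K-AKT pathway list were called: 5 of 30 rose and 3 fell (5 and 3 adjusted over the list alone). Camera did not call that list (adjusted p = 0.47, and adjusted p = 0.89 with an estimated correlation). Without untreated BSC11 replicate 2, DEPTOR stood at -0.7.

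The averaged count of 4753 genes moved by over 1.5 times when any 1 of the 8 libraries was left out, to 7927 and 7496 without an untreated BSC11 library and to 2352 to 3108 without one of the other 6. With the trend on transcript length and GC content removed, 60.8% of the called genes were higher, against 45.5% in the main test, and the median of all genes moved to 0.11. No list that camera called changed the sign of its median under RLE, library totals or that trend.

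**Figure D2:**
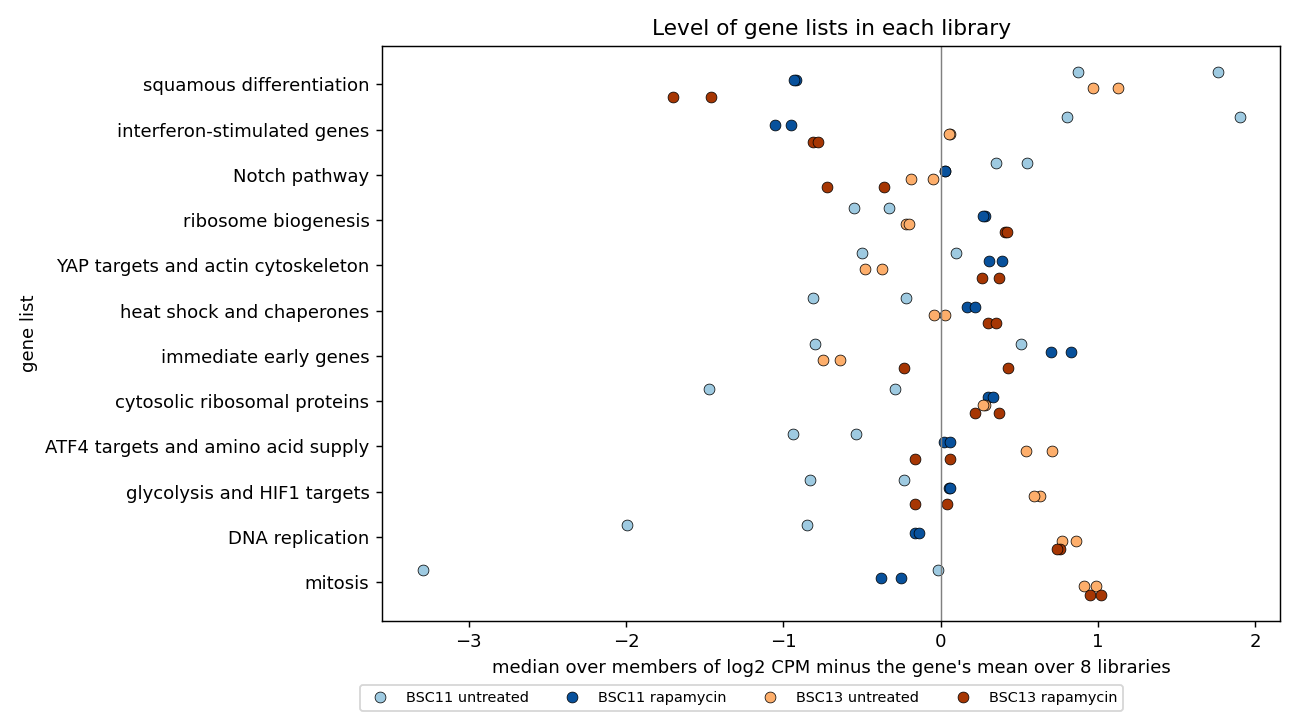
Level of 12 gene lists in each of the 8 libraries; the x axis is the median over list members of log2 CPM minus the gene's mean over the 8 libraries, and points are coloured by line and agent. The squamous differentiation list lies at 0.87 to 1.76 in the 4 untreated libraries and at -1.7 to -0.92 in the 4 rapamycin libraries, while the mitosis list differs most between the untreated BSC11 libraries (-0.02 and -3.29).

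In BSC11 alone, rapamycin was accompanied by a fall of interferon-stimulated and squamous genes and a rise of genes that supply growth: cytosolic ribosomal proteins, amino acid supply and the proteasome. Interferon-stimulated genes fell in 27 of 31 (29 adjusted over the list alone), with a median of -2.72 (camera adjusted p = 3.7e-08, and adjusted p = 0.58 with an estimated correlation). Squamous genes fell in 32 of 51 (37 fell and 1 rose adjusted over the list alone), with a median of -2.6 (camera adjusted p = 3.2e-08, and adjusted p = 0.58 with an estimated correlation). Genes of cytosolic ribosomal proteins rose in 18 of 36 (20 adjusted over the list alone, camera adjusted p = 2.3e-06, and adjusted p = 0.66 with an estimated correlation), and in 36 without untreated BSC11 replicate 1 and 27 without replicate 2. ATF4 targets, which supply amino acids, rose in 16 of 29 and fell in 2 (17 and 2 adjusted over the list alone, camera adjusted p = 0.00015, and adjusted p = 0.58 with an estimated correlation). Proteasome genes rose in 17 of 27 (19 adjusted over the list alone, camera adjusted p = 0.00012, and adjusted p = 0.58 with an estimated correlation).

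In all, 2548 genes rose and 2882 fell in BSC11. Since the pooled spread is smaller than that of the untreated BSC11 pair, these calls are less certain than their p-values state. With that in view, 3242 genes were called with one weight per group, a fit added after seeing the data, and 2683 in a fit of the BSC11 libraries alone. The count was 8385 without untreated BSC11 replicate 1, 2557 and 1998 without BSC11 rapamycin replicate 1 and 2, and with the length and GC trend removed 59.6% of calls were higher, against 46.9%.

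In BSC13 squamous genes were lower with rapamycin too, and amino acid supply and glycolysis genes were lower. Squamous genes fell in 38 of 51 (42 adjusted over the list alone), with a median of -2.75 (camera adjusted p = 1.5e-23, and adjusted p = 0.4 with an estimated correlation). ATF4 targets fell in 8 of 29 (14 adjusted over the list alone, camera adjusted p = 3.2e-06, and adjusted p = 0.46 with an estimated correlation). Genes of glycolysis and HIF1 targets fell in 7 of 28 (13 adjusted over the list alone, camera adjusted p = 1.1e-05, and adjusted p = 0.62 with an estimated correlation). In the fit of BSC13 alone, 23 of 29 and 19 of 28 fell. Ribosome biogenesis genes rose in 15 of 31 (19 adjusted over the list alone, camera adjusted p = 3.2e-07, and adjusted p = 0.12 with an estimated correlation). YAP targets rose in 11 of 28 (17 adjusted over the list alone, camera adjusted p = 1.2e-06, and adjusted p = 0.46 with an estimated correlation). Interferon-stimulated genes fell in 5 of 31 (10 adjusted over the list alone, camera adjusted p = 0.0017, and adjusted p = 0.75 with an estimated correlation), and in 14 of 25 in the fit of BSC13 alone. With untreated BSC11 replicate 1, or likewise replicate 2, left out, 23 ATF4 targets, 19 glycolysis genes and 17 interferon-stimulated genes fell and 20 YAP targets rose. KRT5 fell from 31500 ± 1410 to 10900 ± 1230 CPM (edgeR adjusted p = 0.0437).

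In all, 902 genes rose and 1055 fell in BSC13. Here the pooled spread exceeds that of the BSC13 pairs, and 4942 genes were called with one weight per group and 5071 in a fit of the BSC13 libraries alone. The count was 5739 and 5760 without an untreated BSC11 library, 880 and 921 without a BSC11 rapamycin library, and 247 to 486 without one of the 4 BSC13 libraries. With the length and GC trend removed 56.6% of calls were higher, against 46.1%.

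The lines differed in how metabolic and growth genes responded, and for most of these lists the untreated lines already differed the other way. The difference between the responses subtracts the difference between the untreated lines, taken from the same libraries. Opposite directions are therefore in part built in and are not a separate result. ATF4 targets had a lower response in BSC13 than in BSC11 in 18 of 29 genes (25 adjusted over the list alone), with a median difference of -1.73 (camera adjusted p = 2.3e-09, and adjusted p = 0.72 with an estimated correlation). Untreated BSC13 held more of them than untreated BSC11, by a median of 1.54. DDIT3, a stress transcription factor downstream of ATF4, rose from 10.6 ± 1.69 to 26.9 ± 1.59 CPM in BSC11 and fell from 103 ± 0.354 to 16.5 ± 0.399 CPM in BSC13 (edgeR adjusted p of the difference 0.000413). Glycolysis and HIF1 target genes had a lower response in BSC13 in 14 of 28 and a higher one in 1 (17 and 1 adjusted over the list alone, camera adjusted p = 9.3e-06, and adjusted p = 0.8 with an estimated correlation). In this list SLC2A1, the glucose transporter, and EGLN3, a HIF hydroxylase, fell in the averaged response, by 1.55 ± 0.14 and 2.95 ± 0.27.

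Further lists had a lower response in BSC13. Untreated BSC13 stood above untreated BSC11 by a median of 0.94 for the proteasome and 0.89 for the respiratory chain. For DNA replication it was 2.19 and for cytosolic ribosomal proteins 1.08. Histones differed less without rapamycin (0.46), and under rapamycin lay at 0.5 and 0.53 in BSC11 and at -1.02 and -1.38 in BSC13. Proteasome genes had one in 15 of 27 (17 adjusted over the list alone, camera adjusted p = 0.00012). In the nuclear respiratory chain it was 10 of 33, with 1 higher (13 and 2 adjusted over the list alone, camera adjusted p = 0.00012). In DNA replication it was 9 of 30, with 1 higher (15 and 2 adjusted over the list alone, camera adjusted p = 0.00013), and in cytosolic ribosomal proteins 7 of 36 (7 adjusted over the list alone, camera adjusted p = 7.5e-05). For each of these the adjusted p was 0.8 with an estimated correlation. Replication-dependent histones had a lower response in 6 of 10 (6 adjusted over the list alone, camera adjusted p = 0.00026, and adjusted p = 0.72 with an estimated correlation). With replicate 1 of untreated BSC11 left out the counts were 28 for the respiratory chain, 27 for DNA replication, 36 for the ribosomal proteins and 25 for glycolysis, and without replicate 2 the first 3 were 22, 16 and 20.

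The squamous list also differed, with 9 of 51 lower and 2 higher (9 and 2 adjusted over the list alone, camera adjusted p = 0.016, and adjusted p = 0.8 with an estimated correlation). Camera no longer called it without untreated BSC11 replicate 1 (adjusted p = 0.72), when 19 were lower and 16 higher, while 31 were lower and 5 higher without replicate 2. Members of the mTOR and PI3K-AKT pathway were lower in 7 of 30 and higher in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.047, and adjusted p = 0.8 with an estimated correlation). Leaving out untreated BSC11 replicate 1, 16 were lower and 4 higher, and without replicate 2 the list was not called (adjusted p = 0.18). A higher response in BSC13 was found for interferon-stimulated genes, which fell less there, in 8 of 31 (8 adjusted over the list alone, camera adjusted p = 0.00037, and adjusted p = 0.8 with an estimated correlation). NF-kB targets had a higher response in 6 of 25 (6 adjusted over the list alone, camera adjusted p = 0.012, and adjusted p = 0.76 with an estimated correlation). Matrix and adhesion genes had one in 9 of 28 and a lower one in 2 (10 and 2 adjusted over the list alone, camera adjusted p = 0.012, and adjusted p = 0.72 with an estimated correlation). In the absence of untreated BSC11 replicate 1 the counts with a higher response were 15 for NF-kB targets and 16 for the matrix list, and without replicate 2 they were 20 for interferon-stimulated genes and 14 for the matrix list.

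The genes with the smallest p for a lower response in BSC13 were NLRP2, an inflammasome protein, ALDH1L2, a mitochondrial folate enzyme, TMTC1, DDIT3 and the clock gene NR1D2. ALDH1L2 rose from 0.606 ± 0.0971 to 49 ± 2.11 CPM in BSC11 and went from 41.9 ± 2.78 to 35 ± 1.75 CPM in BSC13. NLRP2 went from 3 counts to 1784 in BSC11, a ratio of 642 (95% counting interval 219 to 3120), and from 78.9 ± 0.378 to 64.1 ± 1.74 CPM in BSC13. The genes with the smallest p for a higher response in BSC13 were IGF2BP3, an mRNA-binding protein, PRKAR2A, a subunit of protein kinase A, the apoptosis inhibitor XIAP, PURB and SPEN. IGF2BP3 fell from 108 ± 23.2 to 0.434 ± 0.216 CPM in BSC11 and went from 8.82 ± 0.196 to 13.8 ± 0.803 CPM in BSC13, a log2 difference of 8.56 ± 0.39 (edgeR adjusted p = 0.00021), or 9.22 without BSC11 rapamycin replicate 2. PURB fell from 71 ± 5.91 to 17.3 ± 1.25 CPM in BSC11 and rose from 9.39 ± 0.0938 to 28.6 ± 1.11 CPM in BSC13.

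In all, the response differed between lines in 2854 genes, 1494 higher and 1360 lower in BSC13. The count was 7399 and 5944 without untreated BSC11 replicate 1 and 2, 772 and 414 without BSC11 rapamycin replicate 1 and 2, 515 and 770 without untreated BSC13 replicate 1 and 2, and 1587 and 865 without BSC13 rapamycin replicate 1 and 2. With library totals as the scale 64.1% of the calls were higher, against 52.3%, since the median of all genes moved to 0.13.

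The responses of the lines, which share no control libraries, were alike in part. Across 12622 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.34, Spearman's rho 0.21 and the covariance 0.53, and 56.6% of genes had the same sign. Of the 1097 genes called in both lines, 359 rose in both and 566 fell in both, against 182 and 241 for independent lists. In 65 genes BSC11 rose and BSC13 fell, and in 107 the reverse, against 213 and 206. Pearson's r was 0.2 without untreated BSC11 replicate 1 and 0.24 with no low-count filter.

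**Figure D3:**
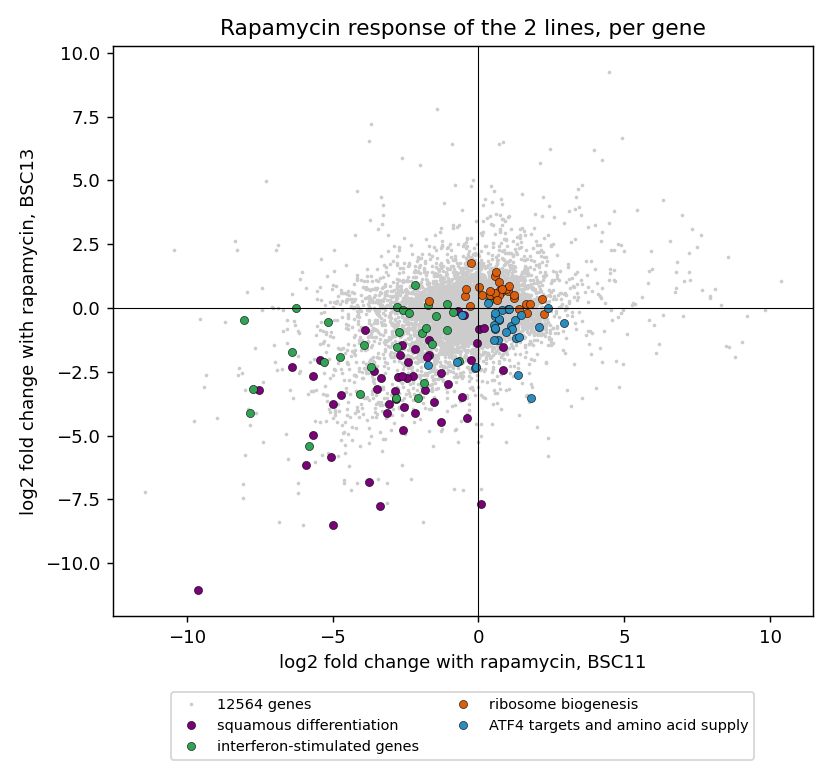
Log2 fold change with rapamycin in BSC11 (x axis) and BSC13 (y axis) for 12564 of the tested genes (grey points), with 4 gene lists in colour. Squamous differentiation genes lie mostly at lower left, with medians of -2.6 in BSC11 and -2.75 in BSC13, and ATF4 targets mostly at lower right, with medians of 0.72 and -0.74; fitted values of genes near 0 counts depend on the prior count.

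Without rapamycin the lines differed in 6128 genes, 2954 higher and 3174 lower in BSC13. Untreated BSC13 held more RNA of DNA replication, with 26 of 30 genes higher and 1 lower, the same counts as adjusted over the list alone (camera adjusted p = 3.9e-08, and adjusted p = 0.61 with an estimated correlation). Proteasome genes were higher in 22 of 27, or 23 adjusted over the list alone (camera adjusted p = 2.9e-07, and adjusted p = 0.48 with an estimated correlation). ATF4 targets were higher in 23 of 29 and lower in 1, with the same counts adjusted over the list alone (camera adjusted p = 2.3e-07, and adjusted p = 0.48 with an estimated correlation). NF-kB targets were lower in BSC13 in 15 of 25, or 17 adjusted over the list alone (camera adjusted p = 0.00057, and adjusted p = 0.48 with an estimated correlation). Interferon-stimulated genes were lower in 18 of 31 and higher in 2, or 20 and 2 adjusted over the list alone (camera adjusted p = 0.0033, and adjusted p = 0.63 with an estimated correlation). Mitochondrially encoded genes, whose share was highest in untreated BSC11 replicate 2, were lower in 10 of 13, or 12 adjusted over the list alone (camera adjusted p = 0.0029, and adjusted p = 0.63 with an estimated correlation). The comparison is of 1 line with 1 other, so it gives the size of a difference between lines and not its source. The count was 2980 and 2943 without untreated BSC13 replicate 1 and 2 and 3725 with one weight per group, and with library totals 37.6% of calls were higher, against 48.2% (median of all genes at -0.14).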

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

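The tests of mesenchymal, endothelial or blood cell RNA, of the growth state, of a single library, of cell composition and of the length and GC trend were chosen only after the results were seen. The last rests on a fit added after the data were seen, though its bounds were written before its own values. Each gene count, list and gene in the next 2 paragraphs was picked out because the rapamycin response differed between BSC11 and BSC13 in a test of the difference itself. The averaged count, the spread of the untreated BSC11 pair and the squamous fall were not picked by that rule and are weighed for their size. Groups of 2 libraries are too small for a test of single outlying samples.

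The response differed between the lines in 2854 genes and, in camera with its preset correlation, in 12 gene lists. With an estimated correlation none of the lists passed (lowest adjusted p = 0.72). The lists with a lower median response in BSC13 were ATF4 targets (-1.73), histones (-1.9), glycolysis and HIF1 targets (-1.21), DNA replication (-1.06), cytosolic ribosomal proteins (-1.01), the nuclear respiratory chain (-0.82), the proteasome (-0.69), mTOR and PI3K-AKT pathway members (-0.46) and squamous differentiation (-0.41). Those with a higher one were interferon-stimulated genes (1.38), NF-kB targets (0.85) and matrix and adhesion genes (0.7). Several medians hung on the untreated BSC11 libraries. Without replicate 1 and without replicate 2 they were -1.77 and -0.48 for cytosolic ribosomal proteins, -2.1 and -0.62 for DNA replication, -0.73 and -0.18 for mTOR pathway members, and -0.18 and -1.56 for squamous differentiation. Without replicate 2 the respiratory chain stood at -0.51 and interferon-stimulated genes at 2.08. With the length and GC trend removed, cytosolic ribosomal proteins stood at -0.63, histones at -1.18 and squamous differentiation at -0.1.

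Of the 63 genes screened by this rule, 26 were picked out. Genes named only in the last section, such as ATG14 and ME1, were not screened, though their responses also lay far apart between the lines. The log2 difference, BSC13 minus BSC11, was negative for NLRP2 (-9.63), TMTC1 (-7.89), ALDH1L2 (-6.6), KRT23 (-6.56), RTL6 (-5.16), DDIT3 (-3.98), IGFBP3 (-3.66), NR1D2 (-3.03), KRT14 (-2.86), ZDHHC2 (-2.75), CDKN1A (-1.55) and UTP4 (-0.72). It was positive for IGF2BP3 (8.56), XIAP (4.77), PRKAR2A (4.75), SPEN (4.29), VIM (3.78), PURB (3.64), IFI44 (3.17), MYC (2.03), SAMD9 (1.79), TGFBI (1.47), AXL (1.17), DNAJA1 (0.7) and PNO1 (0.67). NLRP2 and ENDOU held 3 counts or fewer in a BSC11 group, so their differences come from counts. The NLRP2 difference has a counting interval of -11.91 to -8.08. Its ratio in BSC11 was 402 (111 to 3320) without untreated BSC11 replicate 1 and 1120 (201 to 44400) without replicate 2. ENDOU had 0 counts with rapamycin in BSC11, and its difference is at least 0.57, so its size is not known.

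The count of genes for the averaged response was set against other splits of the 8 libraries into 4 and 4. With a model of line plus split, 1 of the 35 splits, the one by rapamycin, gave a count as large (2014 genes). The highest other count was 360, for the split by line, which was fitted without a line term, and the next was 5. By the bound set before, fewer than 5% of the splits, chance would have been excluded, but that bound was made stricter after the counts were seen. Of the splits, 32 break up replicate pairs, which may share a culture, and only 3 keep all pairs whole, too few to exclude chance whatever their counts, so it stays open.

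The untreated BSC11 libraries differed more than the other pairs. With the trend on transcript length and GC content removed, the SD of their log2 differences was 0.92, against at most 0.3 in the other pairs, which argues against that trend as the whole source. RNA of mesenchymal, endothelial or blood cells is argued against by 7 genes abundant there, of which the highest, VIM, reached 1.05 CPM. A first version of that set gave no decision and was revised after its values were seen, leaving out SPARC (68.37 and 24.35 CPM) and COL1A1 (8.11 and 5.62 CPM), which epithelial cells may also express. A different growth state of the cultures stays open as a hypothesis: the difference of the mitosis list, a median of 3.26, prompted it and so does not test it.

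Interferon-stimulated genes fell more in BSC11 than in BSC13. Within BSC11, the list's median lay above the rapamycin libraries by 2.85 in untreated replicate 1 and 1.75 in replicate 2 (log2 scale). The fall within BSC11 was therefore not in 1 library alone, but that measure does not compare the lines. The list's level was 1.9 and 0.8 in untreated BSC11 replicates 1 and 2, against 0.06 and 0.05 in untreated BSC13. How far the larger fall rests on replicate 1 stays open. Blood cell RNA is argued against by 5 genes, of which the highest reached 0.0749 CPM. With the length and GC trend removed the median difference was 1.26, against 1.38 before. A difference between the lines themselves, or between their untreated cultures, stays open and was not tested.

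The squamous differentiation list fell in both lines. With the length and GC trend removed its median was -2.68, against -2.74 before, so that trend does not account for it. The alternative that rapamycin cultures held fewer differentiated cells among otherwise unchanged basal cells would leave the basal cell list at or above 0. Its median was -0.46, with a 95% interval over members that ended at -0.02, but with the trend removed, a bound added after the first was seen, it ended at 0.06. Fewer differentiated cells and lower expression within each cell therefore cannot be told apart with these bulk libraries.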

How the results depend on the processing

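The voom fit with one weight per group, the fit with the length and GC trend removed and list counts without single libraries were chosen only after the results were seen. DESeq2, voom, RLE, library totals, both filters and the trend-removed fit kept the counts of called genes within 1.5 times. The genes turned over more than the counts with the trend removed: of the called genes 86.6%, 79.9%, 89.4%, 67.9% and 72.5% stayed called with the same sign for the average, BSC11, BSC13, the difference and the untreated lines, and 21, 84, 0, 29 and 245 changed sign. Whether the replicate numbers pair the libraries stays open. The deviations correlated at 0.08 within BSC11 and 0.28 within BSC13, against -0.24 to -0.02 between lines. With the replicate number as a block the counts were 4200, 5029, 1356, 2115 and 5756 in the same order, and 66.2% of the BSC13 calls were kept.

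Against a 1.5-fold change the counts were 1384, 2692, 657, 1254 and 3140 in that order, lower because the test asks for more. The additive model called 2014 genes for the average and the model without the line 789. In the additive model, which has no term for a difference between lines, KRT23, RTL6, IGFBP3, MYC and MKI67 kept their direction but were not called (adjusted p = 0.0621, 0.133, 0.114, 0.215 and 0.112). Separate fits called 2683 genes in BSC11 and 5071 in BSC13. One weight per group gave 3242 in BSC11, 4942 in BSC13 and 3725 between the untreated lines. With the correlation estimated per list, 0 lists passed camera for the average, 0 for BSC11, 0 for BSC13 and 0 for the difference, and unadjusted p was below 0.05 in 4, 3, 3 and 2 lists. Fry called 17, 20, 15 and 10. For the average, fry did not call some lists that camera called. These were immediate early genes (fry adjusted p = 0.064), DNA replication (0.15), cytosolic ribosomal proteins (0.19), the nuclear respiratory chain (0.19) and mitochondrially encoded genes (0.23). Nor did fry call cytosolic ribosomal proteins in BSC11 (0.083) or interferon-stimulated genes in BSC13 (0.22).

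Leaving out 1 library, with the lone library assumed to vary like the other groups, gave 2352 to 7927 genes for the average, 1998 to 8385 for BSC11, 247 to 5760 for BSC13, 414 to 7399 for the difference and 2943 to 9051 for the untreated lines. Pearson's r between the lines ranged from 0.2 to 0.39 and was 0.24 with no low-count filter. Of 652 values of named genes under alternatives, 609 kept direction and side of the threshold, 20 lost a call, 12 gained one and 11 changed direction. The last were in genes that were not called: MTOR (0.01 in DESeq2, 0 in voom, 0.01 with RLE, 0.02 with no filter, 0 with the block, -0.03 to 0.04 leaving out a library), RPTOR (0.03 without the line, -0.21 to 0.18), NGFR (-0.91 to 1.06), CXCL8 (-0.54 to 0.36) and DEPTOR (-0.7 to 0.18), and the cause was not tested. Depth limits genes such as IL6, with 9 counts in 8 libraries.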

Other observations

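The gene contrast of the lines under rapamycin was chosen only after the results were seen. Several gene lists fixed before the data were examined are not described above, and in most of them members went both ways in the averaged response. In the TGF-beta and BMP target list 9 of 30 genes rose and 13 fell (10 and 14 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 0.82, and adjusted p = 0.93 with an estimated correlation). Among p53 targets 7 of 25 rose and 5 fell (7 and 6 adjusted over the list alone), with a median of 0.1 (camera adjusted p = 0.73, and adjusted p = 0.93 with an estimated correlation). NRF2 targets rose in 5 and fell in 6 of 25 (5 and 6 adjusted over the list alone, camera adjusted p = 0.49, and adjusted p = 0.93 with an estimated correlation). Wnt pathway genes rose in 4 and fell in 5 of 18 (4 and 6 adjusted over the list alone, camera adjusted p = 0.93, and adjusted p = 0.93 with an estimated correlation). In the unfolded protein response 1 of 22 genes rose and the others were not called (1 adjusted over the list alone, camera adjusted p = 0.8, and adjusted p = 0.93 with an estimated correlation). These counts changed when replicate 1 or 2 of untreated BSC11 was left out, which can in part come from the shared spread. Without replicate 1, 12 p53 targets rose and 7 fell, 14 NRF2 targets rose and 7 fell, 5 Wnt pathway genes rose and 8 fell, and 1 gene of the unfolded protein response rose and 11 fell. Without replicate 2, 8 p53 targets rose and 10 fell, 8 NRF2 targets rose and 9 fell, 7 Wnt pathway genes rose and 6 fell, and 3 genes of the unfolded protein response rose and 3 fell. The median of the TGF-beta and BMP list was then -0.04. With all libraries and the length and GC trend removed it was -0.02.

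Autophagy genes rose in 6 and fell in 4 of 28, the same counts as adjusted over the list alone (camera adjusted p = 0.51, and adjusted p = 0.87 with an estimated correlation). SQSTM1, an autophagy receptor, rose by 1.54 ± 0.3 in the average (2.18 ± 0.44 in BSC11, 0.9 ± 0.42 and not called in BSC13). In untreated BSC11 SQSTM1 stood at 62.84 and 178.62 CPM, so the size of its rise there depends on the library. MAP1LC3B, which encodes LC3B of the autophagosome membrane, rose by 0.69 ± 0.11, while ATG14 fell by 2.73 ± 0.43. ATG14 had a log2 fold change of -5.3 ± 0.63 in BSC11 and of -0.16 ± 0.59 in BSC13, where it was not called in edgeR (adjusted p = 0.888). Lysosome genes rose in 4 and fell in 5 of 32, the same counts as adjusted over the list alone (camera adjusted p = 0.82, and adjusted p = 0.93 with an estimated correlation). Fatty acid synthesis genes rose in 2 and fell in 3 of 13 (2 and 3 adjusted over the list alone, camera adjusted p = 0.83, and adjusted p = 0.93 with an estimated correlation). ACSS2 and ACLY, which make cytosolic acetyl-CoA, rose by 1.21 ± 0.1 and 1.14 ± 0.14, while ME1 and the regulator SREBF1 fell, with log2 fold changes of -1.11 ± 0.11 and -1.07 ± 0.15. The average of ME1 came from BSC11 (-2.03 ± 0.16), and in BSC13 it was not called (-0.19 ± 0.16, edgeR adjusted p = 0.455). With untreated BSC11 replicate 1 left out, 13 autophagy genes rose and 5 fell, 7 lysosome genes rose and 12 fell, and 7 fatty acid synthesis genes rose and 4 fell. With replicate 2 left out the counts were 9 and 8, 14 and 7, and 5 and 5.

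Markers of other lung cells were tested in part. Ciliated cell markers rose in 4 and fell in 2 of 22 tested (4 and 2 adjusted over the list alone, camera adjusted p = 0.75, and adjusted p = 0.88 with an estimated correlation), and alveolar and lung lineage markers rose in 3 and fell in 4 of 12 (3 and 5 adjusted over the list alone, camera adjusted p = 0.93, and adjusted p = 0.93 with an estimated correlation). Fibroblast markers rose in 4 and fell in 3 of 12 (4 and 4 adjusted over the list alone, camera adjusted p = 0.83, and adjusted p = 0.93 with an estimated correlation). Leaving out untreated BSC11 replicate 1, 6 ciliated, 4 alveolar and 3 fibroblast markers rose and 4, 5 and 5 fell. Leaving out replicate 2, 7, 5 and 5 rose and 6, 5 and 4 fell. Of 20 leukocyte, 15 endothelial and 16 ionocyte or neuroendocrine markers, 1, 2 and 3 passed the count filter, too few for a list test.

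Under rapamycin the lines differed in 971 genes, 420 higher and 551 lower in BSC13, with an SD of log2 fold changes of 0.93 over all genes, against 6128 genes and an SD of 1.47 without rapamycin. Pearson's r between libraries of different lines was 0.948 to 0.962 under rapamycin and 0.825 to 0.893 without it. The count without rapamycin includes the untreated BSC11 pair, whose spread was the largest.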
